A study of Mus musculus with 48 samples.

How the data were processed

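Total RNA of liver, heart, gastrocnemius muscle and white adipose tissue was hybridised on 48 glass arrays of 70mer oligos, 12 per tissue. Per the labels, each array carried labelled cDNA of 1 high-fat mouse and of the pooled chow mice of the same tissue, and the dyes (Alexa Fluor dyes, read in the Cy3 and Cy5 channels) were exchanged on a second array. The deposited scanner files hold, per the file headers, the mean intensity and the local background intensity of every spot in both channels, with the standard deviation of the background pixels and a mark for spots to be ignored. The deposited series matrix holds log2 ratios made by the authors, whose exact normalization is not stated. Set against the scanner files, these were high-fat over chow in direction and near 0 in their column medians (-0.04 to 0.22).

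Each array had 14592 spots, which hold 6868 gene oligos spotted 2 times each, 792 blank and 60 randomized negative control spots. The files give accessions and gene names but no symbols, so 567 oligos were named through the RefSeq table of accessions and symbols and 820 from the gene names; 5481 oligos have no symbol here. The map from names was extended after the first fits, by the gene names alone, for genes called or in a gene list. Which oligos have a symbol thus depended in part on the calls. Of the called oligos, 91 of 116 had a symbol in liver, 27 of 30 in heart, 45 of 53 in muscle and 183 of 226 in adipose tissue. Genomic positions were not available.

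Scanner intensities were read with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) and analysed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package 1.17.8; figures were drawn with matplotlib 3.10.9. Background was corrected by the normexp model with an offset of 50, and log ratios were normalised within each array by loess (span 0.3), with control spots at weight 0 and marked spots left out. Log ratios were turned to high-fat over chow, the spots of an oligo averaged, and the 2 arrays of a replicate averaged, so that n counts animals. An oligo was to be detected, at 2 standard deviations above the local background in either channel, on 6 of the 12 arrays of a tissue. This filter removed no oligo, so all 6868 were tested. A filter on the 95th percentile of the negative controls, chosen after seeing the data, keeps 5171 oligos in liver, 5889 in heart, 3298 in muscle and 5547 in adipose tissue.

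In each tissue the mean log ratio was tested against 0 with limma (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all oligos and a threshold of 0.05. At an unadjusted p below 0.05, 818 oligos stood in liver, 855 in heart, 1126 in muscle and 1074 in adipose tissue. Because the chow pool is 1 sample, a test against 0 leaves out the spread between chow mice. Differences between tissues were contrasts in 1 fit of all 24 replicates. Calls in common were compared with the product of the 2 numbers of calls over the number of oligos. The chow pools of the tissues are separate, but chow mice may be shared between them. A deviation of shared chow mice would then appear in several tissues. The test takes replicates as independent, although the animal codes in the titles show that 5 animals gave both heart and muscle and 4 both liver and adipose tissue; same-animal ratios correlated at 0.00 and -0.06 on average. In 2 of those 4, adipose replicates 1 and 2, title and file name give different codes, and the titles were used.

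Lists of genes for pathways and cell types, 36 in number with 1121 memberships, were drawn up, and 711 memberships had an oligo. They were tested with limma's camera at a preset correlation of 0.01, 1 oligo per gene, the brightest. Camera compares a list with the other oligos. Fry asks whether a list's genes move, on balance, in 1 direction and does not compare them with other genes.

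The genes named were chosen by a rule. This rule, the gene lists, the tests and the other settings to be tried were fixed before the data were examined. Per tissue it takes the 12 largest rises and 12 largest falls among oligos with a symbol, past the threshold and of the same sign in all 6 replicates. It adds the 2 largest differences in each direction per pair of tissues, at most 20 genes called alike in the most tissues, and at most 4 members per list and tissue with the smallest adjusted p. The rule asks for a single symbol per oligo, which for most oligos here came from a gene name in place of an accession.

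Slide lots, 4 in number, were read from the slide numbers, and 6 scan batches from gaps of more than 21 days between scans; neither is given in the labels. A replicate was put to the lot and batch of its array with high-fat in Cy5. The settings tried were no background subtraction, median centring, print-tip loess, scaling between arrays, no filter and a stricter one, marked spots kept, the deposited log2 values, each dye orientation alone, a trended and robust variance model, slide lot or scan batch as a block or each alone, leaving out each replicate, all tissues in 1 fit, a fold threshold of 1.5, blocks by replicate number or animal code, camera with an estimated correlation, fry, and the mean over the oligos of a gene. Alternatives chosen after seeing the data were the filter on negative controls and the turning or leaving out of 1 adipose array.

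The procedure was tested on simulated data with the same layout. The simulated genes varied independently and alike in every tissue, with no error of the chow pool and no array turned round. In the data the median SD of an oligo was 0.29 in liver, 0.23 in heart, 0.27 in muscle and 0.36 in adipose tissue. The percentages recovered are thus not the power in a given tissue. Changes of 1 or 2 on the log2 scale were recovered in 100% of genes in each tissue, and changes of 0.5 in 68.4% in liver, 67.2% in heart, 71.6% in muscle and 52.2% in adipose tissue, with 7 to 13 false calls among 6868 oligos. Differences between tissues of 1 or more were recovered in 97.3% to 99.2%. A list simulated as shifted in liver was called, and in muscle and adipose tissue 1 other list each was called falsely.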

Results

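Messenger RNA levels were compared in 4 tissues of male C57BL/6J mice, an inbred laboratory strain, after 20 weeks on a high-fat or a chow diet. The high-fat diet held 15% protein, 59% fat and 26% carbohydrate, and the chow 23%, 21% and 55%. Liver, heart, skeletal muscle (gastrocnemius) and white adipose tissue were taken after a fast of 6 h. Each tissue had 6 high-fat replicates, 1 animal each, and every replicate was hybridised on 2 arrays with the dyes exchanged, so that 48 arrays hold 24 replicates. The reference channel of each array was cDNA pooled from the chow mice of the same tissue, so the chow group is 1 pooled sample per tissue and the spread between chow animals was not measured. The values are log2 ratios of high-fat over chow pool, given as the mean ± SD of n = 6 replicates unless stated, and the number of arrays limits their precision. Between 1870 and 6614 of the 6868 gene oligos were brighter than the negative controls on an array (27.2% to 96.3%). Hearts were scanned in a period of their own and most adipose arrays in another, so scan time and tissue are nearly confounded.

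What the high-fat diet changed in liver was the first question. Apoa4 (oligo M001654), which encodes an apolipoprotein made in intestine and liver, rose most among the named genes, by 3.12 ± 0.43 (8.67-fold, adjusted p = 8.77e-07, higher in 6 of 6 replicates). Cd36, a fatty acid transporter, rose by 1.45 ± 0.50 and Apoc2, the cofactor of lipoprotein lipase, by 1.09 ± 0.33. Cyp26a1, which breaks down retinoic acid, was lower at -2.52 ± 0.76. Its high-fat channel was above the negative controls on only 1 of 12 arrays. Igfbp2, a binding protein of insulin-like growth factors, was lower at -1.22 ± 0.22 and Selenbp1 at -1.10 ± 0.10, both in 6 of 6 replicates. In all, 62 oligos rose and 54 fell in liver, 110 of the 116 with the same sign in all 6 replicates (limma, Benjamini-Hochberg).

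Genes of xenobiotic metabolism moved both ways in liver. Cyp2b9 (1.42 ± 0.36) and Cyp2b13 (1.25 ± 0.59) rose, while Cyp2c29 (-1.65 ± 0.41) and Cyp2c37 (-1.04 ± 0.30) fell. Of the 56 measured members of the xenobiotic metabolism list, 2 rose, 6 fell and 48 did not pass (3 rose and 11 fell adjusted over the list alone). Cyp7b1, an oxysterol hydroxylase, was lower at -1.21 ± 0.72, Hsd3b4, a steroid dehydrogenase, at -1.16 ± 0.49 and Hacl1, an enzyme of fatty acid alpha-oxidation, at -0.995 ± 0.25. Among 11 measured genes of cholesterol synthesis, Cyp51 (-0.54 ± 0.24) and Ebp (-0.42 ± 0.12) fell, no gene rose and 9 did not pass. Adjusted over the list alone, 4 of them fell. On the arrays with high-fat in Cy5 alone, Cyp51 in liver stood at 0.01.

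The PPAR target genes, which respond to fatty acid receptors of the nucleus, shifted upward in liver with a median of 0.27 over 18 members, a call that ended with an estimated correlation (adjusted p = 0.262). Cd36 and Plin2, which coats lipid droplets (0.79 ± 0.38), rose and 16 members did not pass, against 8 that rose adjusted over the list alone. Acute phase genes rose in 5 of 20 measured members, among them Saa2 (1.12 ± 0.36), Saa1 (1.04 ± 0.38) and Lcn2 (1.27 ± 0.64), and 6 rose and 1 fell adjusted over the list alone. The collagen genes Col3a1 (1.11 ± 0.54) and Col1a1 (1.07 ± 0.25) rose out of 50 extracellular matrix genes, 6 adjusted over the list alone. Mpeg1 (0.61 ± 0.14), Lgmn (0.49 ± 0.10), Tyrobp (0.46 ± 0.16) and Spp1 (0.98 ± 0.73) were the 4 of 34 macrophage and lysosome genes that rose, with 9 adjusted over the list alone. Lgals1 (1.46 ± 0.42), Gpc1 (1.29 ± 0.58) and Anxa5 (1.06 ± 0.45) also rose. Lag3 (-1.14 ± 0.61), Raet1d (-1.05 ± 0.59), Ccl25 (-1.03 ± 0.48) and Nxf1 (-1.03 ± 0.53) fell.

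Of the 36 gene lists, 13 shifted in liver relative to the other oligos (camera, preset correlation), 9 upward and 4 downward. The upward lists were the PPAR targets (adjusted p = 1.03e-05), macrophage and lysosome genes (median 0.14, adjusted p = 1.03e-05), acute phase proteins (0.16, 2.22e-04), extracellular matrix (0.14, 4.34e-04), glycolysis (0.15, 0.00766), adipocyte markers (0.07, 0.0136), antigen presentation (0.10, 0.0143), fatty acid oxidation (0.19, 0.0154) and the tricarboxylic acid cycle (0.24, 0.0209). Cholesterol synthesis (-0.24, 8.41e-05), xenobiotic metabolism (-0.11, 0.00232), hepatocyte markers (-0.11, 0.00316) and ribosomal proteins (-0.11, 0.00316) shifted downward. With an estimated correlation none of these calls was kept, with adjusted p = 0.25 for cholesterol synthesis, 0.321 for fatty acid oxidation and for xenobiotic metabolism, 0.387 for antigen presentation and 0.262 for each of the other 9.

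Fewer oligos were called in liver without replicate 1 (77), 4 (71), 5 (45) or 6 (53), and replicates 1, 3, 4 and 5, taken as 1 slide lot by their arrays with high-fat in Cy5, gave 36 against 116 over all 6. Cyp7b1 lost its call without replicates 4, 5 or 6, Raet1d without 1, 5 or 6, and the other 22 named genes of liver kept theirs whichever replicate was left out.

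**Figure D1:**
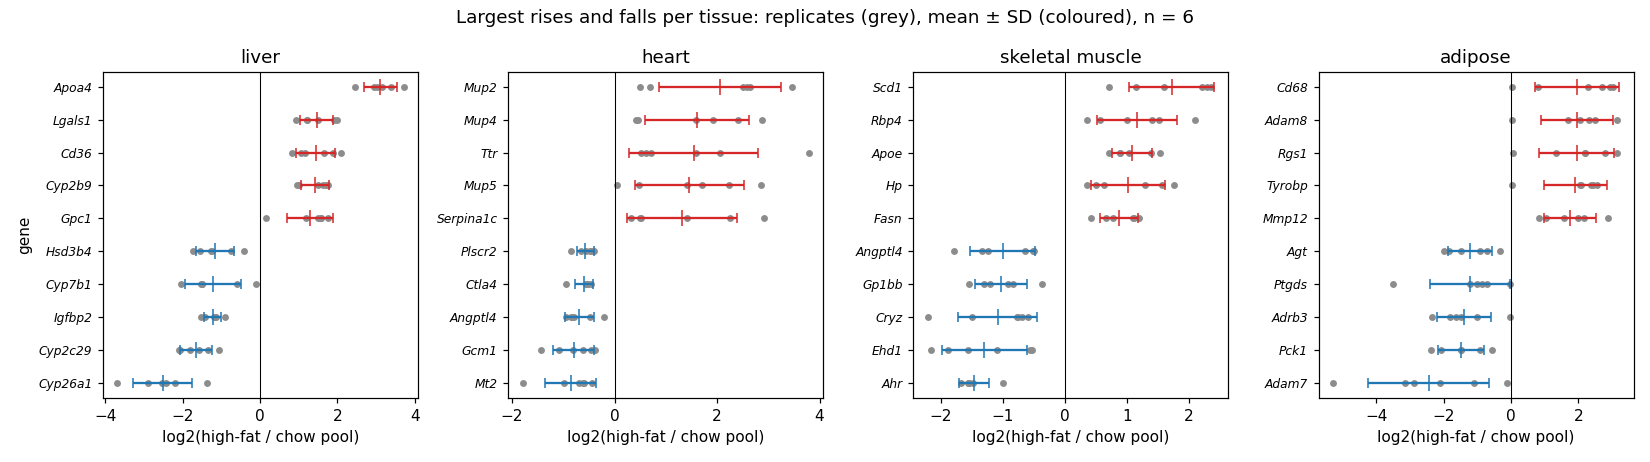
Log2 ratio of high-fat over chow pool for the named genes of each tissue, with a point per replicate (n = 6) and bars of the mean ± SD, for the 5 largest rises and falls. Apoa4 in liver stands at 3.12 and Cyp26a1 at -2.52.

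In heart, Nppb, the natriuretic peptide released by strained heart muscle, rose by 1.01 ± 0.41 (oligo M000951, 2.01-fold, adjusted p = 0.00611, higher in 6 of 6 replicates). Acta1, the skeletal alpha-actin gene, rose by 0.70 ± 0.28, so 2 of the 13 measured cardiac stress genes rose. Adjusted over the list alone, 2 rose and 2 fell; Nppa stood at -0.86 ± 0.69 and was lower in 5 of 6 replicates (adjusted p = 0.0547 over all genes). Angptl4, an inhibitor of lipoprotein lipase, was lower at -0.69 ± 0.28 and Mt2, a metal-binding protein, at -0.85 ± 0.50. Gcm1 (-0.80 ± 0.40), Ctla4 (-0.60 ± 0.17), Plscr2 (-0.57 ± 0.17), Ehd1 (-0.55 ± 0.30), Oprk1 (-0.54 ± 0.25) and Fgf12 (-0.48 ± 0.19) were lower as well. Acot1 (0.48 ± 0.19), an acyl-CoA thioesterase, rose among 18 PPAR targets together with Fabp1, and Angptl4 fell (4 rose and 2 fell adjusted over the list alone).

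The other genes that rose most in heart encode proteins that the liver makes. The hepatocyte list rose in 11 of 24 measured members (16 adjusted over the list alone) with a median of 0.53 (adjusted p = 7.49e-20), which ended with adjusted p = 0.466 with an estimated correlation. Major urinary protein genes led it, with Mup2 at 2.06 ± 1.19, Mup4 at 1.61 ± 1.01, Mup5 at 1.46 ± 1.06 and Mup1 at 0.96 ± 0.72. Transthyretin (Ttr, 1.55 ± 1.26), liver fatty acid binding protein (Fabp1, 1.29 ± 0.82) and the alpha-1 antitrypsin genes Serpina1c (1.32 ± 1.07), Serpina1d (1.13 ± 0.89), Serpina1b (1.03 ± 0.69) and Serpina1a (0.83 ± 0.64) rose too. The liver-rich oligos outside this list, 100 in number, had a median of 0.17 in heart, with 86 of them above 0. In Mup2 the replicates ranged from 0.50 to 3.46. The other 35 lists did not shift in heart by camera, while fry called the smooth muscle and mesothelial markers there.

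**Figure D2:**
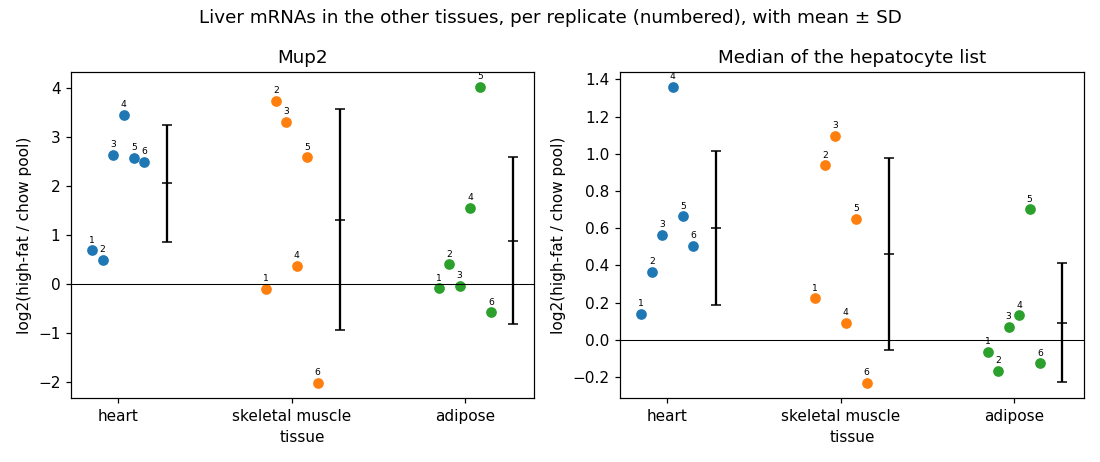
Log2 ratio of high-fat over chow pool of Mup2 and of the median of the hepatocyte list in heart, skeletal muscle and adipose tissue, with points numbered by replicate and bars of the mean ± SD (n = 6). Mup2 was above 0 in 6 of 6 hearts, from 0.50 to 3.46.

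Altogether 30 oligos were called in heart, 19 higher and 11 lower. Without background subtraction 13 were called, 6 higher and 7 lower. The deposited log2 values gave 0 calls in limma against 739 at an unadjusted p below 0.05, replicates 1, 2, 4 and 6 of 1 slide lot gave 1, and leaving out replicate 2, 3 or 5 gave 15, 11 or 1, the last being Nppb.

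**Figure D3:**
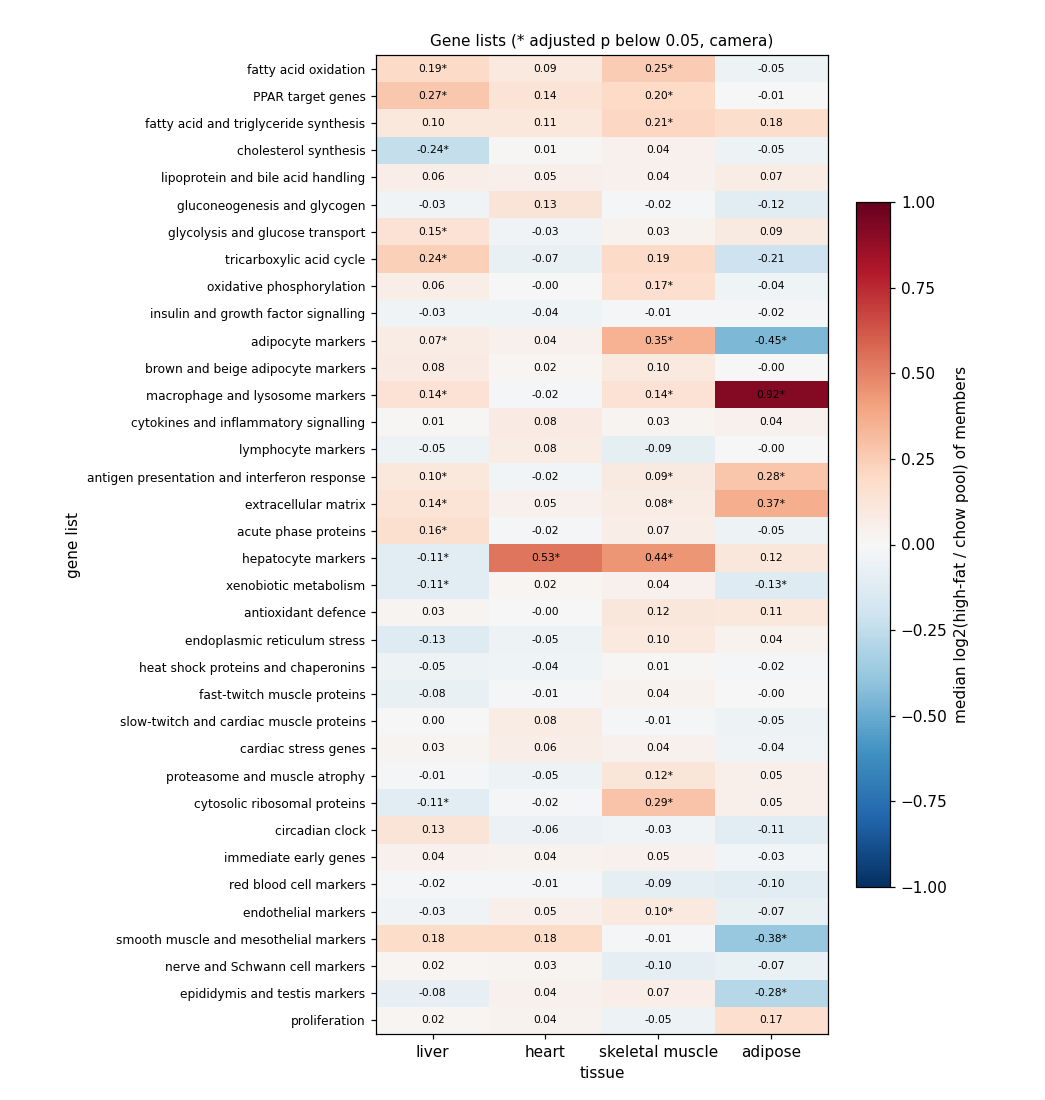
Median log2 ratio of each of the 36 gene lists in each tissue, where colour and number give the median and an asterisk an adjusted p below 0.05 in camera. The median of the hepatocyte list was 0.53 in heart and that of the macrophage list 0.92 in adipose tissue.

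In skeletal muscle 2 genes of fatty acid synthesis rose. Scd1, the desaturase that makes monounsaturated fatty acids, rose by 1.72 ± 0.68 (oligo M006300, 3.29-fold, adjusted p = 0.00449, higher in 6 of 6 replicates), and fatty acid synthase (Fasn) by 0.87 ± 0.31. Apolipoprotein E (Apoe) rose by 1.07 ± 0.32. The aryl hydrocarbon receptor gene Ahr was lower at -1.47 ± 0.24 (adjusted p = 1.2e-04, lower in 6 of 6). Of the 53 oligos called in muscle, 26 rose and 27 fell, and with median centring in place of loess 14 rose and 24 fell.

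Among 9 measured genes of fatty acid and triglyceride synthesis, Scd1 and Fasn rose and 7 did not pass, against 4 that rose adjusted over the list alone. In the PPAR target list, Plin2 (0.74 ± 0.34) and Fabp3 (0.72 ± 0.35), the muscle fatty acid binding protein, rose and Angptl4 (-1.01 ± 0.53) fell, with 5 higher and 2 lower adjusted over the list alone. Of 14 genes of fatty acid oxidation none passed over all genes in limma (8 at an unadjusted p below 0.05), while Acadvl (0.44 ± 0.21), Slc25a20 (0.39 ± 0.15) and Eci1 (0.37 ± 0.14) passed adjusted over the list alone. Ech1 (0.86 ± 0.40) and Dbi (0.74 ± 0.33), which bind or convert acyl-CoA, rose. The adipocyte marker Adipoq rose by 0.68 ± 0.33, 1 of 13 in its list, with 5 adjusted over the list alone. The median of that list was above 0 in 6 of 6 muscles (0.35 ± 0.23), so the rise of Scd1 and Fasn in muscle fibres is not told apart from more fat cells in the samples. From the hepatocyte list only Rbp4 rose, and 9 members rose adjusted over the list alone. The chow channel of Rbp4 was above the negative controls on 0 of 12 arrays. With the dimmest signal above those controls as a floor for that channel, its rise was 1.94-fold. This is an estimate and not a strict limit. The largest rise of all in muscle was that of an oligo without a symbol, a serum albumin variant (2.21), which was called in heart too (1.76). Mup2 ranged from -2.02 to 3.74 over the muscle replicates. Haptoglobin (Hp, 1.02 ± 0.60), Lgals3 (0.85 ± 0.51) and H2-Q2 (0.80 ± 0.33) rose as well.

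Ehd1 (-1.30 ± 0.68), Cryz (-1.09 ± 0.64), Gp1bb (-1.03 ± 0.41), Ccs (-0.93 ± 0.54), Asgr1 (-0.93 ± 0.52), Spint1 (-0.90 ± 0.40), Bhlha15 (-0.79 ± 0.30) and Fancc (-0.70 ± 0.36) were lower in muscle. The high-fat channel of Il17rb was above the negative controls on 0 of 12 arrays. With the same kind of floor for that channel, Il17rb was 1.67-fold lower, again an estimate.

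In muscle 12 of the 36 lists shifted, all upward. The smallest adjusted p was that of the ribosomal protein genes (median 0.29, adjusted p = 7.35e-10), of which 0 of 25 passed over all genes (limma, 20 at an unadjusted p below 0.05) and 15 passed adjusted over the list alone, Rps19 at 0.40 ± 0.26 among them. Hepatocyte markers (0.44, 4.01e-07), fatty acid oxidation (0.25, 1.64e-06), fatty acid and triglyceride synthesis (0.21, 7.58e-05), adipocyte markers (0.35, 1.30e-04), macrophage genes (0.14, 0.00155), oxidative phosphorylation (0.17, 0.00265), proteasome genes (0.12, 0.00745), PPAR targets (0.20, 0.0129), extracellular matrix (0.08, 0.0207), antigen presentation (0.09, 0.0317) and endothelial markers (0.10, 0.0485) followed. None kept its call with an estimated correlation: adjusted p = 0.356 for ribosomal proteins, 0.426 for antigen presentation, 0.357 for hepatocyte, endothelial, matrix and oxidative phosphorylation genes, and 0.269 for the other 6.

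Replicate 6 stood apart in muscle: the array with its high-fat sample in Cy5 correlated at -0.14 across oligos with the mean of the other replicates, and 197 oligos were called without that replicate. Leaving out replicate 1, 2, 3, 4 or 5 gave 25, 6, 9, 6 or 5 calls, replicates 1, 2, 4 and 5 of 1 slide lot gave 20, and only Ahr, Apoe, Il17rb and Scd1 of the 24 named genes stayed called whichever replicate was left out. With slide lot as a random block 6 oligos were called in muscle and with scan batch 1 (Ahr), all of them among those 24.

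White adipose tissue had the most calls, with 177 oligos higher and 49 lower. Macrophage genes rose: Cd68 by 1.97 ± 1.25 (oligo M003093, 3.91-fold, adjusted p = 0.00496, higher in 6 of 6 replicates), Tyrobp by 1.92 ± 0.94, the macrophage elastase Mmp12 by 1.76 ± 0.76 and Itgax, which encodes CD11c, by 1.498 ± 0.871. Adrb3, the beta-3 adrenergic receptor of fat cells, was lower at -1.39 ± 0.80, and Pck1, an enzyme of glyceroneogenesis, at -1.48 ± 0.67. Adam7, a gene of the epididymis, was lowest at -2.44 ± 1.79 with all arrays as labelled. The adipose array of replicate 1 with the high-fat sample in Cy3 ran against the other 11 (correlation -0.48 with the mean of the other replicates), and its direction is not settled. With its ratio turned 563 oligos were called, 386 higher and 177 lower, and with the array left out 522, of which 365 were higher. Adam7 stood at -2.76 with the array turned and -3.11 with it left out. The values here keep the array as labelled.

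The macrophage and lysosome list rose in 19 of 34 measured members (24 adjusted over the list alone), with a median of 0.92 (adjusted p = 8.82e-24) and a replicate median above 0 in 6 of 6; with an estimated correlation the call ended (adjusted p = 0.511). Cathepsin D (Ctsd, 1.14 ± 0.47) was among them, as was Lgals3 (2.20 ± 1.21, higher in 5 of 6). Adam8 (1.96 ± 1.06), Rgs1 (1.96 ± 1.11), Lilrb4a (1.63 ± 0.61), C5ar1 (1.56 ± 1.00) and the complement gene C1qc (1.61 ± 0.83), which leukocytes express, rose too. Of 26 genes of antigen presentation and the interferon response 5 rose, H2-Eb1 (0.96 ± 0.58) and Mx2 (0.70 ± 0.42) among them, 5 also adjusted over the list alone. Lumican (Lum, 1.68 ± 0.81), Mgp (1.06 ± 0.37) and Col1a1 (1.24 ± 0.53) were among 10 of 50 extracellular matrix genes that rose, with 1 that fell, and 23 rose and 1 fell adjusted over the list alone. Plin2 rose by 1.67 ± 0.82 and Evl by 1.58 ± 0.61.

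Adipocyte markers fell in 4 of 13 members, with 7 adjusted over the list alone: Cfd, which encodes adipsin (-2.07 ± 1.07, lower in 5 of 6), Adrb3, Adipoq (-1.01 ± 0.80, lower in 5 of 6) and Car3 (-1.69 ± 1.65, lower in 5 of 6). Krt19 (-0.98 ± 0.62) and Acta2 (-0.65 ± 0.25) fell among 11 smooth muscle and mesothelial markers, 3 adjusted over the list alone. Adam7 was the 1 of 14 epididymis and testis genes that fell (5 adjusted over the list alone), and Cst8 (-1.56 ± 1.81) and Gpx5 (-1.69 ± 2.24), both lower in 5 of 6 replicates, did not pass over all genes. With the doubtful array turned or left out, Cst8 (-2.35 or -2.27), Gpx5 (-2.53 or -2.35) and Prm2 (-1.07 or -1.15) passed too. So did Krt18 (-1.21 or -1.24) and Myh11 (-0.64 or -0.65). Ptgds (-1.22 ± 1.19), Agt (-1.21 ± 0.66), Apcdd1 (-1.18 ± 0.56), Zfp185 (-1.12 ± 1.01), Epcam (-1.01 ± 0.92), Igfbp5 (-0.89 ± 0.54), Ccl21b (-0.89 ± 0.50) and Sgcd (-0.86 ± 0.36) were lower in 6 of 6. Sult1a1 was lower at -0.65 ± 0.32, but with the doubtful array turned it stood at -0.47 (adjusted p = 0.155).

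Lists shifted upward in adipose tissue were the macrophage genes, the extracellular matrix (median 0.37, adjusted p = 2.52e-08) and antigen presentation (0.28, 5.29e-06). Downward shifts were found for adipocyte markers (-0.45, 5.66e-05), epididymis and testis genes (-0.28, 0.00222), smooth muscle and mesothelial markers (-0.38, 0.00274) and xenobiotic metabolism (-0.13, 0.00612), of which 2 of 56 members fell (7 adjusted over the list alone). None of the 7 kept its call with an estimated correlation (adjusted p = 0.511 with an estimated correlation for each).

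Leaving out replicate 1, 2, 4, 5 or 6 gave 354, 137, 88, 94 or 92 calls in adipose tissue, and 17 of the 24 named genes stayed called throughout. The calls lost were Adam7 without replicate 4 (-2.35, adjusted p = 0.0521 for Adam7 in adipose), Krt19 without 5, Ccl21b without 4 or 5, Igfbp5 without 4, 5 or 6, Ptgds and Zfp185 without 3, 4, 5 or 6 and Epcam without 1, 3, 4, 5 or 6. The deposited log2 values gave 0 calls in limma (797 at an unadjusted p below 0.05), the arrays with high-fat in Cy3 alone gave 0 (601), and replicates 1, 2, 3 and 6 of 1 scan batch gave 0 (674).

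**Figure D4:**
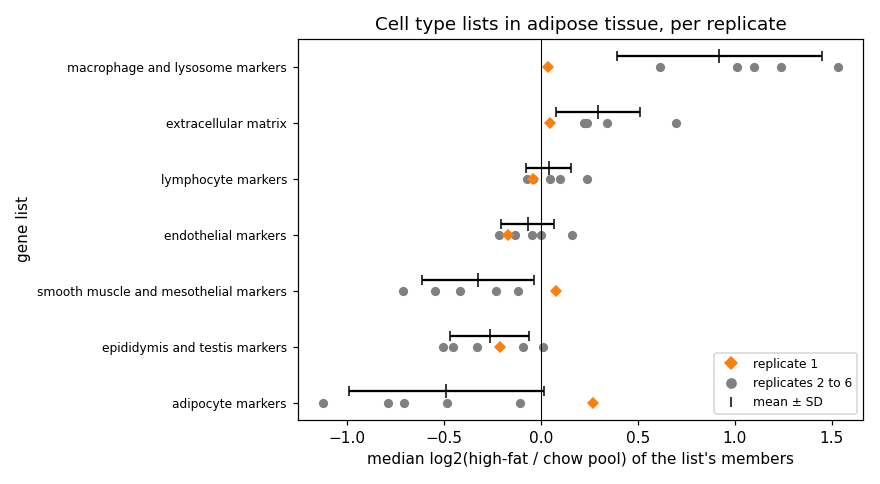
Median log2 ratio (high-fat over chow pool) of cell type gene lists, with a point per adipose replicate and bars of the mean ± SD over 6 replicates. The macrophage median was above 0 in 6 of 6 replicates, and the smooth muscle and mesothelial median in 1 of 6.

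Whether tissues responded alike was asked of the calls they had in common. Plin2 rose in liver, muscle and adipose tissue (0.79, 0.74 and 1.67), and so did the collagen gene Col3a1 (1.11, 0.66 and 1.21). Liver and adipose tissue had 15 higher oligos in common against 1.60 expected of independent lists, among them Col1a1, Mpeg1, Hexa, Lilr4b, Ctsa, Lgmn, Vim, H2-Eb1, Tyrobp and Lgals3bp. Muscle and adipose tissue had 10 in common against 0.67, with the class I genes H2-Q2, H2-Q7 and H2-Q10, Hp and Lgals3. Angptl4 and Ehd1 fell in both heart and muscle against 0.04 expected of independent samples, although 5 animals gave both tissues, and Sult1a1 was lower in heart and adipose tissue, a call lost in adipose tissue with the doubtful array turned. In all, 29 oligos were called the same way in 2 or more tissues, 25 higher and 4 lower. Only 2 were called in 3 tissues. No oligo was called in 4. Calls in opposite directions were Mt2 for liver and heart, Cyp2b9 and Cryz for liver and muscle, Plagl1 and Bche for liver and adipose tissue, and Adipoq and Fhl3 for muscle and adipose tissue.

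The number in common was 18 without liver replicate 5, 18 without muscle replicate 2, 3 or 4, 17 without muscle replicate 5, 46 without muscle replicate 6, and 19 or 16 without adipose replicate 4 or 6. The deposited log2 values gave 8 and the arrays with high-fat in Cy3 alone gave 2.

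A test of the difference itself asked where the response differed between tissues. The rise of Apoa4 was larger in liver than in heart (difference 2.39, standard error 0.30, adjusted p = 4.79e-06), muscle (2.70) and adipose tissue (2.83). Cyp26a1 differed between liver and these tissues by -2.52, -2.17 and -2.27, values that rest on a high-fat signal near the negative controls in liver, and Cyp2c29 by -1.76 in heart and -1.85 in muscle. Cyp2b9, which was higher in 6 of 6 livers, was lower in muscle in 6 of 6 replicates (-0.52), a difference of 1.94. Mt2 was higher in 5 of 6 livers (0.87) and lower in 6 of 6 hearts (-0.85), a difference of 1.72. Lcn2 (2.65) and Adam8 (-1.95) differed between liver and adipose tissue as well.

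Heart and muscle differed in 5 oligos, with Scd1 (-1.46) and Apoe (-1.01) more positive in muscle and Ahr (1.14) and Gp1bb (0.97) less. Heart minus adipose tissue, the response differed in Adam7 (2.49), Cfd (2.33), Lgals3 (-2.13) and Tyrobp (-2.12). Muscle minus adipose tissue, it differed in Cfd (2.62), Adam7 (2.61), Tyrobp (-2.04) and Cd68 (-1.96). Differences numbered 81 between liver and heart (38 more positive in liver), 154 between liver and muscle (73 in liver), 390 between liver and adipose tissue (155 in liver), 287 between heart and adipose tissue (90 in heart) and 367 between muscle and adipose tissue (151 in muscle). With the doubtful array turned, the 3 counts with adipose tissue were 649, 558 and 577, in the order liver, heart, muscle, and with it left out 657, 557 and 610.

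By the animal codes in the titles, 4 animals gave both liver and adipose tissue and 5 both heart and muscle, while the test takes the 24 replicates as independent. No code of liver or adipose tissue recurs in heart or muscle. Between these tissues, a difference of tissue cannot be told apart from a difference between sets of animals. For 2 of the 4, adipose replicates 1 and 2, the code in the file name differs from that in the title, so these pairs are uncertain. Tested as pairs, these animals alone gave 3 differences between liver and adipose tissue and 3 between heart and muscle; with the code as a random block over all replicates the counts were 359 and 5.

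With slide lot as a fixed block the counts were 6 for liver and heart, 11 for liver and muscle, 54 for liver and adipose tissue, 3 for heart and muscle, 4 for heart and adipose tissue and 23 for muscle and adipose tissue; with scan batch as a fixed block they were 1 for liver and muscle, 19 for liver and adipose tissue and 35 for muscle and adipose tissue, and the fit could not be made for heart, which was scanned apart. No lot or batch holds 3 replicates of each of 2 tissues. Differences within 1 of them, given with the other settings, had 1 or 2 replicates in an arm and decide nothing. The count for liver and heart was 49 without liver replicate 6, and that for liver and muscle 99 or 86 without liver replicate 1 or 6 and 83 or 86 without muscle replicate 2 or 5. For heart and muscle it was 3 without heart replicate 1, 2, 3, 4 or 6 or muscle replicate 4, and for heart and adipose tissue 463 without adipose replicate 1.

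**Figure D5:**
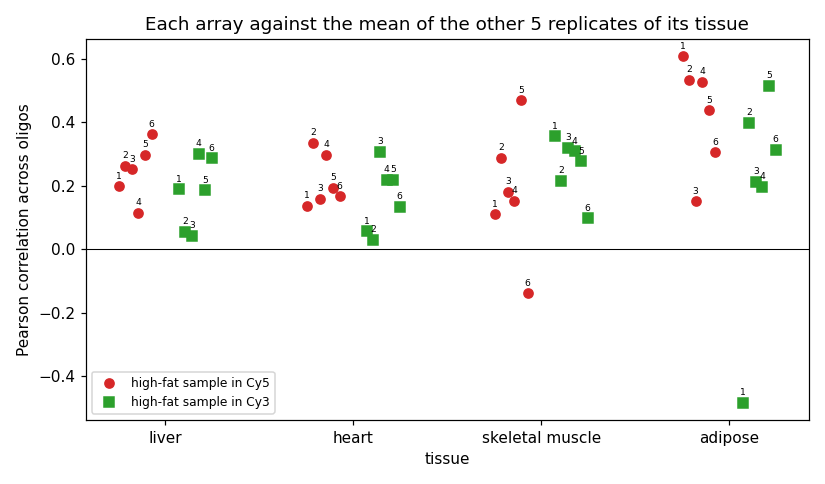
Pearson correlation across oligos of the log2 ratios of each array with the mean of the other 5 replicates of its tissue, with points numbered by replicate and marked by dye. The 1 adipose array at -0.48 runs against the other adipose arrays, and 1 muscle array stands at -0.14.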

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

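The counts over other splits of the replicates, the tests of the adipose array and the tests of adipose cell types were chosen after the results were seen; the liver-rich oligos and the dye orientations in heart were fixed before their result was seen.

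Replicates far from the other 5 were looked for in 253 groups of 6 values, 27 were found, and chance gives about 1 in 20 groups (12.7). In liver these were Acadm in replicate 2 (-0.30), Col1a1 in 6 (1.54), Cyp51 in 2 (-0.0857), Eno3 in 6 (0.0168), Gpc1 in 2 (0.16), Rps24 in 5 (-0.00361), Saa1 in 1 (1.75), Slc2a5 in 1 (0.93) and Spp1 in 6 (2.39). Ctla4 stood apart in heart replicate 1 (-0.94), and Ahr (-0.995) and Eci1 (0.64) in muscle replicate 4. Adipose replicate 2 was lowest in Epcam (-2.79), Krt18 (-3.18), Prm2 (-2.42) and Ptgds (-3.51). Adipose replicate 1 stood apart in Adipoq (0.56), Car3 (1.58), Cfd (0.0065), Col3a1 (-0.0645), Ctsa (-0.41), Evl (0.38), Lgmn (-0.82), Lum (0.15), Mpeg1 (-0.20) and Tyrobp (0.0328), and in the correlation of its array with high-fat in Cy3 (-0.48).

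The adipose array of replicate 1 with high-fat in Cy3 is the first pattern weighed. Of the 200 oligos with the largest mean ratio in the other 5 replicates, only 3% had the same sign on it, and over all oligos it correlated at -0.48 with their mean. A noisy hybridisation gives a correlation near 0, which the latter value excludes. Channels labelled the wrong way round may account for it: the other array of the replicate correlates at 0.61. The array with high-fat in Cy3 had a median background of 0 in Cy5 and 612 in Cy3. On every other adipose array the background was higher in Cy5. Exchanged channels would give this order. A mix-up of samples does not predict it but is not excluded. No biological explanation was tested.

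Liver proteins' mRNAs in heart are the second. The 100 oligos with the largest excess of liver over heart signal were taken without the hepatocyte list and the named heart genes. They had a median log2 ratio of 0.17 in heart, above 0 in 6 of 6 replicates (exact sign-flip test, two-sided p = 0.0312, the smallest that 6 replicates allow). Equally dim oligos had a median of 0.01 and were above 0 in 6 of 6 too, so that test does not separate the 2 sets. The liver-rich median was above theirs in 6 of 6 replicates. A dye effect is excluded, as the lower of the hepatocyte medians over both orientations was 0.58. Liver RNA in the heart samples is a candidate explanation whose prediction was met. For muscle and adipose tissue the 100 oligos were picked anew, by the excess of liver signal over that tissue. Their medians were 0.14 in muscle (above 0 in 5 of 6) and -0.01 in adipose tissue. A response of the heart to the diet stays open, as untested.

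Macrophage genes higher and other cell type genes lower in adipose tissue are the third. The doubtful array alone is excluded, since the lower macrophage median with it turned or left out was 1.18. A smaller share of adipocytes alone would raise the markers of every other cell type. On average over replicates, the endothelial median was -0.07 (standard error 0.06) and the lymphocyte median 0.04 (standard error 0.05). The extracellular matrix median was 0.29 (standard error 0.09). The smooth muscle and mesothelial median was -0.32 on average over replicates (standard error 0.12) and the macrophage median 0.92 (standard error 0.22). A smaller share of adipocytes alone would require all of these cell type lists to rise, and they did not. Epididymis and testis genes shifted downward too. A smaller share of adipocytes together with less of another tissue in the samples is therefore not weighed by these values. More macrophages, or more of these transcripts per cell, may account for the rise; the diet is an open explanation, and neither was tested.

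Turning the signs of the replicates makes 32 splits. For genes, 1 of 32, the real split, gave as many calls in each tissue, which is the smallest share that 32 splits allow. Counts were 116 in liver (highest other 0), 30 in heart (0), 53 in muscle (14) and 226 in adipose tissue (205). All 6 ratios of a tissue share 1 chow pool, so turning signs cannot exclude a chance deviation of that pool. The split with 205 turns adipose replicate 1 alone and points to the structure of that replicate. For lists, only the real split gave as many in liver (1 split, 13 lists, highest other 10). Other splits gave as many in heart (22 splits, 1 list, highest other 8) and muscle (3 splits, 12 lists, highest other 12). They did so in adipose tissue too (6 splits, 7 lists, highest other 10), so chance cannot be excluded for the lists of these 3 tissues. For the 29 oligos in common, 1 of 100 joint turns gave as many (highest other 1). A turn left 0 calls in liver or heart and at most 14 in muscle, so few were left to share. The joint turns thus do not test whether calls overlap more than chance.

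The response differed between tissues, by a test of the difference, in 81 oligos for liver and heart, 154 for liver and muscle, 390 for liver and adipose tissue, 5 for heart and muscle, 287 for heart and adipose tissue and 367 for muscle and adipose tissue. In 1 of 100 regroupings, the real one, the count was as large for each pair, with highest others of 6, 108, 287, 4, 232 and 287. For heart and muscle the margin was only 5 against 4. Replicates of a tissue share a chow pool, so regrouping cannot exclude a chance deviation of a pool. The regroupings take no account of slide lot, scan batch or shared animals. With slide lot as a fixed block the counts were 6, 11, 54, 3, 4 and 23, so a batch effect on the counts is not excluded for any pair, and for heart scan batch and tissue cannot be told apart. Of the 24 named differences 14 stayed called with that block, Apoa4 in liver against each other tissue among them. Named differences for liver minus heart were Apoa4 (2.39), Mt2 (1.72), Cyp26a1 (-2.52, from a high-fat liver signal above the negative controls on 1 of 12 arrays) and Cyp2c29 (-1.76), and for liver minus muscle Apoa4 (2.70), Cyp2b9 (1.94), Cyp26a1 (-2.17) and Cyp2c29 (-1.85). Liver minus adipose tissue gave Apoa4 (2.83), Lcn2 (2.65), Cyp26a1 (-2.27) and Adam8 (-1.95), and heart minus muscle Ahr (1.14), Gp1bb (0.97), Scd1 (-1.46) and Apoe (-1.01). Heart minus adipose tissue gave Adam7 (2.49), Cfd (2.33), Lgals3 (-2.13) and Tyrobp (-2.12), and muscle minus adipose tissue Cfd (2.62), Adam7 (2.61), Tyrobp (-2.04) and Cd68 (-1.96).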

How the results depend on the processing

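The filter on negative controls and the turned or left-out adipose array were chosen after seeing the data; all others were set beforehand. The cause of a change was not tested unless stated. Leaving out 1 replicate or keeping 1 lot, batch or dye leaves fewer samples or arrays. All 92 genes named for the size of their change kept their direction under every alternative run. Calls were compared over every alternative set beforehand other than leaving out 1 replicate. Those within 1 lot or batch, which hold fewer replicates, were counted. Under all of these, 17 of 24 in liver, 1 of 24 in muscle and 0 in heart and adipose tissue kept their call. Signal over background limits the dim oligos: only 48.0% of oligos in muscle were above the negative controls on 6 of 12 arrays, and ratios of dimmer ones are compressed by the offset.

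No background subtraction gave 217 genes in liver, 13 in heart (6 higher, 7 lower), and differences of 130 for liver and heart, 291 for liver and muscle and 98 for heart and muscle. Median centring gave 2 lists in heart (1 higher, 1 lower), and print-tip loess 16 genes and 2 lists in heart, 8 differences of heart and muscle and, in adipose tissue, 10 lists (6 higher, 4 lower). Scaling between arrays gave 82 genes in muscle, 138 differences of liver and heart and 39 of heart and muscle. The deposited log2 values gave 231 genes in liver, 0 in heart and 0 in adipose tissue (limma, 739 and 797 unadjusted), 8 oligos in common and 53 differences of liver and heart (17 more positive, 36 more negative), with 320 of liver and adipose tissue split 93 and 227, 4 of heart and muscle split 4 and 0, and 7 adipose lists split 4 and 3. The trended and robust variance gave 227 genes in liver, 18 in heart, 85 in muscle and 44 in common.

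Arrays with high-fat in Cy5 alone gave 20 genes in muscle and 552 in adipose tissue, differences of 146 (liver and heart), 76 (liver and muscle) and 686 (liver and adipose tissue) and 7 lists in liver. Those with high-fat in Cy3 alone gave 66 genes in liver, 7 in heart, 105 in muscle and 0 in adipose tissue (601 unadjusted), 15, 64 and 49 differences of liver from heart, muscle and adipose tissue, 0 of heart from muscle and from adipose tissue (limma, 602 and 577 unadjusted), 23 of muscle and adipose tissue, 2 oligos in common and 3, 6 and 4 lists in heart, muscle and adipose tissue. Values that changed sign, none of them past the threshold there, were Serpina1a in liver (0.042 with print-tip loess, 0.0452 with the deposited values), Cyp51 in liver (0.00957) and Aqp7 in muscle (-0.49) with Cy5 alone, and Col14a1 (-0.12) and Pfkl (-0.28) in liver with Cy3 alone.

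Slide lot as a random block gave 172 genes in heart and 6 in muscle, and scan batch 1 in muscle and 725 in adipose tissue. Within 1 lot or batch, genes numbered 36 in liver, 1 in heart (2 lists), 20 in muscle and 0 in adipose tissue (limma, 674 unadjusted). Slide lot as a fixed block left 6, 11, 54, 3, 4 and 23 differences for liver and heart, liver and muscle, liver and adipose tissue, heart and muscle, heart and adipose tissue, and muscle and adipose tissue; scan batch left 1 for liver and muscle, 19 for liver and adipose tissue and 35 for muscle and adipose tissue, and cannot be fitted for heart. Differences within a lot or batch had 1 or 2 replicates in an arm and say nothing about it: heart and muscle gave 0 in lot 2 (2 and 4 replicates, limma, 438 unadjusted) and 27 in lot 1 (4 and 1), liver and heart 3 (1 and 4), liver and adipose tissue 2 in lot 4 (1 and 6) and 2 in batch 5 (1 and 4), and muscle and adipose tissue 0 in lot 4 (1 and 6, limma, 458 unadjusted) and 35 in batch 6 (1 and 2). A replicate was put to the lot and batch of its array with high-fat in Cy5; in liver replicate 1 and muscle replicate 6 the other array differs. Counts within 1 tissue were not run in lots and batches with fewer than 3 replicates, nor was slide lot as a block in adipose tissue or scan batch in heart, which hold 1 each.

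All tissues in 1 fit gave 18 genes in heart, 146 in muscle, 786 in adipose tissue and 47 in common. Only 2 tissues in the fit gave 131, 162, 8, 169 and 132 differences for liver and heart, liver and adipose tissue, heart and muscle, heart and adipose tissue, and muscle and adipose tissue. By the codes in the titles a replicate number marks 1 animal in 2 of 6 cases for heart and muscle, 1 of 6 for liver and adipose tissue and 0 of 6 for other pairs, and correlations of same-number replicates ran from -0.14 to 0.15, so the numbers were not taken as a pairing. A block by replicate number gave 182 (liver and adipose tissue), 2 (heart and muscle), 170 (heart and adipose tissue) and 92 (muscle and adipose tissue); pairing by shared animal codes gave 3 for liver and adipose tissue (4 animals, 2 of them with uncertain codes) and 3 for heart and muscle (5 animals). The code as a random block (consensus correlation -0.04) moved no count by over 1.5 times.

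With an estimated correlation camera called 0 lists in liver, heart, muscle and adipose tissue (4, 3, 5 and 2 unadjusted). Fry called 11 in liver, 9 of them called by camera, 1 in heart (smooth muscle and mesothelial markers, not called by camera), 5 in muscle, 3 of them called by camera, and 0 in adipose tissue (10 unadjusted). Above the negative controls 96 genes were called in muscle. With the adipose array turned, 563 genes were called in adipose tissue and its differences were 649 (liver), 558 (heart) and 577 (muscle), and with it left out 522, 657, 557 and 610.

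Leaving out 1 replicate gave 45 to 93 genes in liver, 1 to 24 in heart, 5 to 197 in muscle and 88 to 354 in adipose tissue, 16 to 46 in common, and 11 to 14, 1 to 6, 10 to 16 and 6 to 8 lists in the same order. Without heart replicate 2 or 5 the heart had 2 or 6 lists. Differences ran from 49 to 90 for liver and heart, 83 to 201 for liver and muscle, 291 to 560 for liver and adipose tissue, 3 to 5 for heart and muscle, 210 to 463 for heart and adipose tissue and 269 to 533 for muscle and adipose tissue. Of all counts under alternatives set beforehand, 260 stayed within 1.5 times the value reported and 127 did not.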

Other observations

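Egr1, an immediate early transcription factor gene, was lower in liver (-0.73 ± 0.24, adjusted p = 0.00627, lower in 6 of 6), and 23 other members of its list did not pass. G6pc, the last enzyme of gluconeogenesis, was lower at -0.60 ± 0.28 in liver and was the 1 of 9 genes of gluconeogenesis and glycogen that fell there. Ppara, the fatty acid receptor gene, rose in liver by 0.47 ± 0.09 and Abcb4, a phospholipid transporter of bile, by 0.50 ± 0.21, both in 6 of 6 replicates. Fbp1, a gene of the liver, rose in heart (0.69 ± 0.40) beside the hepatocyte list (median 0.53), and Fbp2 in muscle (0.56 ± 0.25). In muscle Gadd45g was lower (-0.67 ± 0.37), and the complement gene C4b (0.55 ± 0.22) and Serpina3n (0.60 ± 0.31) rose.

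In adipose tissue Pltp (1.28 ± 0.63) and Lcat (1.01 ± 0.71), which act on plasma lipoproteins, rose as 2 of 17 genes of lipoprotein and bile acid handling. Hmox1, which degrades heme, rose by 0.86 ± 0.47 and Jchain, a gene of plasma cells, by 0.81 ± 0.51, the 1 of 29 lymphocyte markers that rose. Cav2, an endothelial and fat cell gene, was lower at -0.54 ± 0.09, in 6 of 6 replicates. The lymphocyte list had medians of -0.05 in liver, 0.08 in heart, -0.09 in muscle and -0.00 in adipose tissue and did not shift by camera in any of the 4.

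Cell type lists that did not shift by camera are given in the order liver, heart, muscle and adipose tissue. Medians were -0.02, -0.01, -0.09 and -0.10 for red blood cell markers, 0.02, 0.03, -0.10 and -0.07 for nerve and Schwann cell markers, and 0.08, 0.02, 0.10 and -0.00 for brown and beige adipocyte markers. Endothelial markers stood at -0.03 in liver, 0.05 in heart and -0.07 in adipose tissue, and smooth muscle and mesothelial markers at 0.18 in liver, 0.18 in heart and -0.01 in muscle. In heart the adipocyte median was 0.04 and the macrophage median -0.02, and the hepatocyte median in adipose tissue was 0.12. Epididymis and testis markers had medians of -0.08 in liver, 0.05 in heart and 0.07 in muscle.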
